A study of Oryza sativa with 8 samples.

How the data were processed

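Shoots of hydroponically grown rice seedlings were profiled on 8 biotin-labelled Affymetrix rice expression arrays, 2 arrays for each of 4 groups. The groups were the varieties Prasanna and Varadan, each in Yoshida nutrient medium without nitrogen or with supplemented nitrogen. Per the labels' protocols, germinated seedlings grew in medium with nitrogen before they were moved to the test media. How long they stayed in the test media is not given in the sources used here, and the age stated for the tissue is shorter than the germination and growth times of the protocol added together.

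Per the submitters' processing notes, signals were summarised with MAS5, whose version is not given in the sources used here. The deposited table holds log2 values for 57381 probe sets, per the file headers. On every array the mean of the linear signals after trimming 2% at each end was 500.0, which is how MAS5 scales arrays to a target. A second deposited table holds the same MAS5 signals as linear intensity values, and their log2 differed from the log2 table by at most 3.0e-08, so the log2 table was used throughout. MAS5 subtracts mismatch signals and gives dim probe sets a large spread on the log2 scale. Scaling all arrays to one target removes any change shared by most transcripts. No scanner files or detection calls were used here. For arrays of this kind the number of arrays limits the precision.

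The 187 Affymetrix control probe sets were left out of the tests and used as measures of RNA quality and hybridisation. Of the other probe sets, 34860 were paired with 1 gene by the platform annotation, 567 with several genes and 21767 with none. No gene was named from a probe set paired with several. The annotation gives locus identifiers without descriptions. Symbols came from a RefSeq gene table (assembly ASM3414082v1), in which the gene IDs of 30586 of the probe sets with 1 gene were found. Of 25727 distinct loci, 2695 had a symbol other than the locus identifier, so most loci are named by identifier alone and no coordinates are given. One probe set stood for each gene, the one with the highest mean log2 over the 8 arrays.

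Probe sets with a mean log2 at or above the 40th percentile (4.48) were tested, which left 34333 probe sets and 21510 loci. A model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), so all comparisons shared 1 estimate of the spread with 4 residual degrees of freedom. The comparisons were no nitrogen against supplemented nitrogen within each variety, the average of these effects, their difference (the interaction), and Varadan against Prasanna at each nitrogen level. Log2 differences of nitrogen are no nitrogen minus supplemented nitrogen, and those of variety are Varadan minus Prasanna. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and errors are standard errors of the fit unless called SD. Tests were 2-sided.

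Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, over 1 probe set per gene, with Benjamini-Hochberg adjustment over the 29 lists that had at least 5 tested genes. The same test with the correlation estimated from the data was run beside it. Limma's fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes, was run in addition and had not been fixed beforehand. The lists cover nitrate uptake and reduction, ammonium uptake and assimilation, amino acid carriers, regulators tied to nitrogen supply, light reactions, carbon fixation with photorespiration, chlorophyll synthesis, chlorophyll breakdown and senescence, autophagy, proteases, cytosolic ribosomal proteins, phenylpropanoids, phosphate starvation, starch and sucrose, organic acids, WRKY and NAC transcription factors, heat shock, peroxidases, glutathione S-transferases, defence proteins, diterpenoids, jasmonate, cytokinin, auxin, the cell cycle, the cell wall, root markers, metal transport, late embryogenesis abundant (LEA) and abscisic acid genes, and aquaporins. Peroxidases and root markers had under 5 tested genes and were not tested as lists.

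The tests, samples, thresholds, alternatives, list themes and the rule for named genes were fixed before the data were examined. List members had been defined by words in gene descriptions. As the annotation holds none, the members were set again from symbols and locus identifiers after the annotation was read and before any expression value of a gene was looked at. Lists of NRT1/PTR carriers and plastid ribosomal proteins were dropped for lack of members, and gene ontology terms were not analysed here. The rule named, from each comparison, the genes with the largest changes in each direction among those past the threshold whose arrays did not overlap between the groups and whose higher group reached the median signal (5.36). It took up to 10 per direction for nitrogen effects, 5 for the interaction and 6 for variety, and filled a direction with fewer than 5 from the smallest unadjusted p. From each list described it took the 4 members with the smallest p. The rule asked for genes with a symbol or description. That this excludes loci known by identifier alone was settled after a listing with such loci had been seen, so loci named by identifier outside the gene lists were chosen after their values were seen.

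Alternatives were quantile normalization, subtraction of each array's median, no filter, a filter at the 60th percentile, no trend in the variance prior, an added 2-fold threshold, array weights, the replicate number as a block, each array left out in turn, the arrays of 1 variety alone, and the mean of all probe sets of a gene for the lists. Leaving out both first no-nitrogen arrays, and a model with nitrogen and variety as additive terms, were added after the data had been seen.

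The code was tested on simulated data with the spread of the arrays. There, 200 probe sets each were changed by 1, 2 and 4 on the log2 scale without nitrogen in both varieties. The comparison within Prasanna recovered 0%, 7.0% and 45.5% of them, with 4 of 109 calls false. For the effect averaged over both varieties the recovered shares were 1.5%, 31.0% and 69.5%, with 10 of 214 calls false. The 1 gene list shifted in the simulation was recovered and 0 of the other lists were called. Probe sets were simulated independently of each other and with the same spread in all groups. The simulation therefore does not measure false calls among lists of coregulated genes or from deviations shared by arrays. Figures and file preparation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.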

Results

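Transcript levels were measured in shoots of rice seedlings of the varieties Prasanna and Varadan, grown in nutrient solution without nitrogen or with supplemented nitrogen, with 2 arrays in each of the 4 groups. The median log2 signal over all probe sets ran from 5.60 to 6.26 across the 8 arrays. Replicate arrays correlated at a Spearman rho, across probe sets, of 0.940 in supplemented Prasanna and 0.939 in supplemented Varadan, and at 0.896 and 0.886 in the groups without nitrogen. The median SD between replicates was 0.31 and 0.26 with supplemented nitrogen and 0.47 and 0.46 without, on the log2 scale. On principal component 2 (24.5% of the variance) the first no-nitrogen arrays stood at 106.8 and 177.8, the others at -86.9 to -9.6. On component 3 (13.6%) the second no-nitrogen arrays stood at 98.7 and 108.6, the others at -94.2 to -3.7. Prasanna without nitrogen, replicate 1, correlated at 0.911 with Varadan without nitrogen, replicate 1, above its 0.896 with its own replicate. Between the second replicates of these groups the correlation was 0.909. A deviation between 2 replicates cannot be placed in either of them. The second no-nitrogen arrays lay close to the supplemented ones, with 0.942 between Prasanna without nitrogen, replicate 2, and supplemented Prasanna, replicate 2, and 0.928 between those of Varadan. A mix-up of samples was not tested. The 18S ribosomal RNA control was brighter on the first than on the second array in every group, by 1.97 and 0.91 log2 without nitrogen and by 1.07 and 0.66 with supplemented nitrogen, in Prasanna and Varadan in turn. The 3' to 5' log2 difference of the glyceraldehyde-3-phosphate dehydrogenase control ran from 2.77 to 2.93 in Prasanna and from 3.87 to 4.78 in Varadan. The same difference on the first no-nitrogen arrays of Prasanna and Varadan was 0.743 and 1.002 for the cyclophilin control, against 1.17 to 1.62 on the other arrays, and -0.01 and -0.12 for the ubiquitin control, against 0.12 to 0.73. For the actin control it was 3.84 and 4.40, against 4.34 to 5.11.

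The first question was which transcripts differ between shoots without and with nitrogen, averaged over both varieties. The nitrate reductase gene NR1 (NIA1, Os08g0468100) fell by 2.68 ± 0.20 on the log2 scale (SE; adjusted p = 0.0218), from 15.69 ± 0.10 (SD, n = 2) to 13.19 ± 0.17 in Prasanna and from 16.14 ± 0.21 to 13.28 ± 0.38 in Varadan. Os01g0357100, the nitrite reductase locus of the nitrate list, fell by 3.71 ± 0.31 (adjusted p = 0.0276). The glutaredoxin GRXC1 fell by 5.32 ± 0.46 (adjusted p = 0.0276) and the non-symbiotic haemoglobin HB2 (NSHB2) by 4.14 ± 0.52 (adjusted p = 0.0476). CHL1 (CHLD), a subunit of the magnesium chelatase that opens the chlorophyll branch, fell by 1.81 ± 0.21 (adjusted p = 0.0376). The urea transporter DUR3 rose by 4.76 ± 0.45 (adjusted p = 0.0328), from 5.73 ± 1.07 to 9.25 ± 0.37 in Prasanna and from 3.29 ± 0.17 to 9.29 ± 0.76 in Varadan. Its supplemented Varadan signal lay under the filter level of 4.48, so the size rests in part on a background signal. ALN, the allantoinase of purine breakdown, rose by 3.31 ± 0.42 (adjusted p = 0.0476). The chlorophyll b reductase NYC1 rose by 2.05 ± 0.25 (adjusted p = 0.0462) and SPX2, of the SPX proteins that sense phosphate supply, by 2.12 ± 0.26 (adjusted p = 0.0476). The actin AC7 (1.26 ± 0.17) and the metallothionein MT4A (-2.43 ± 0.33) had an adjusted p of 0.053 and did not pass. For each gene said to rise or fall here, both no-nitrogen arrays lay on 1 side of both supplemented arrays within each variety. The rule for named genes required this, so it is no further support.

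**Figure D1:**
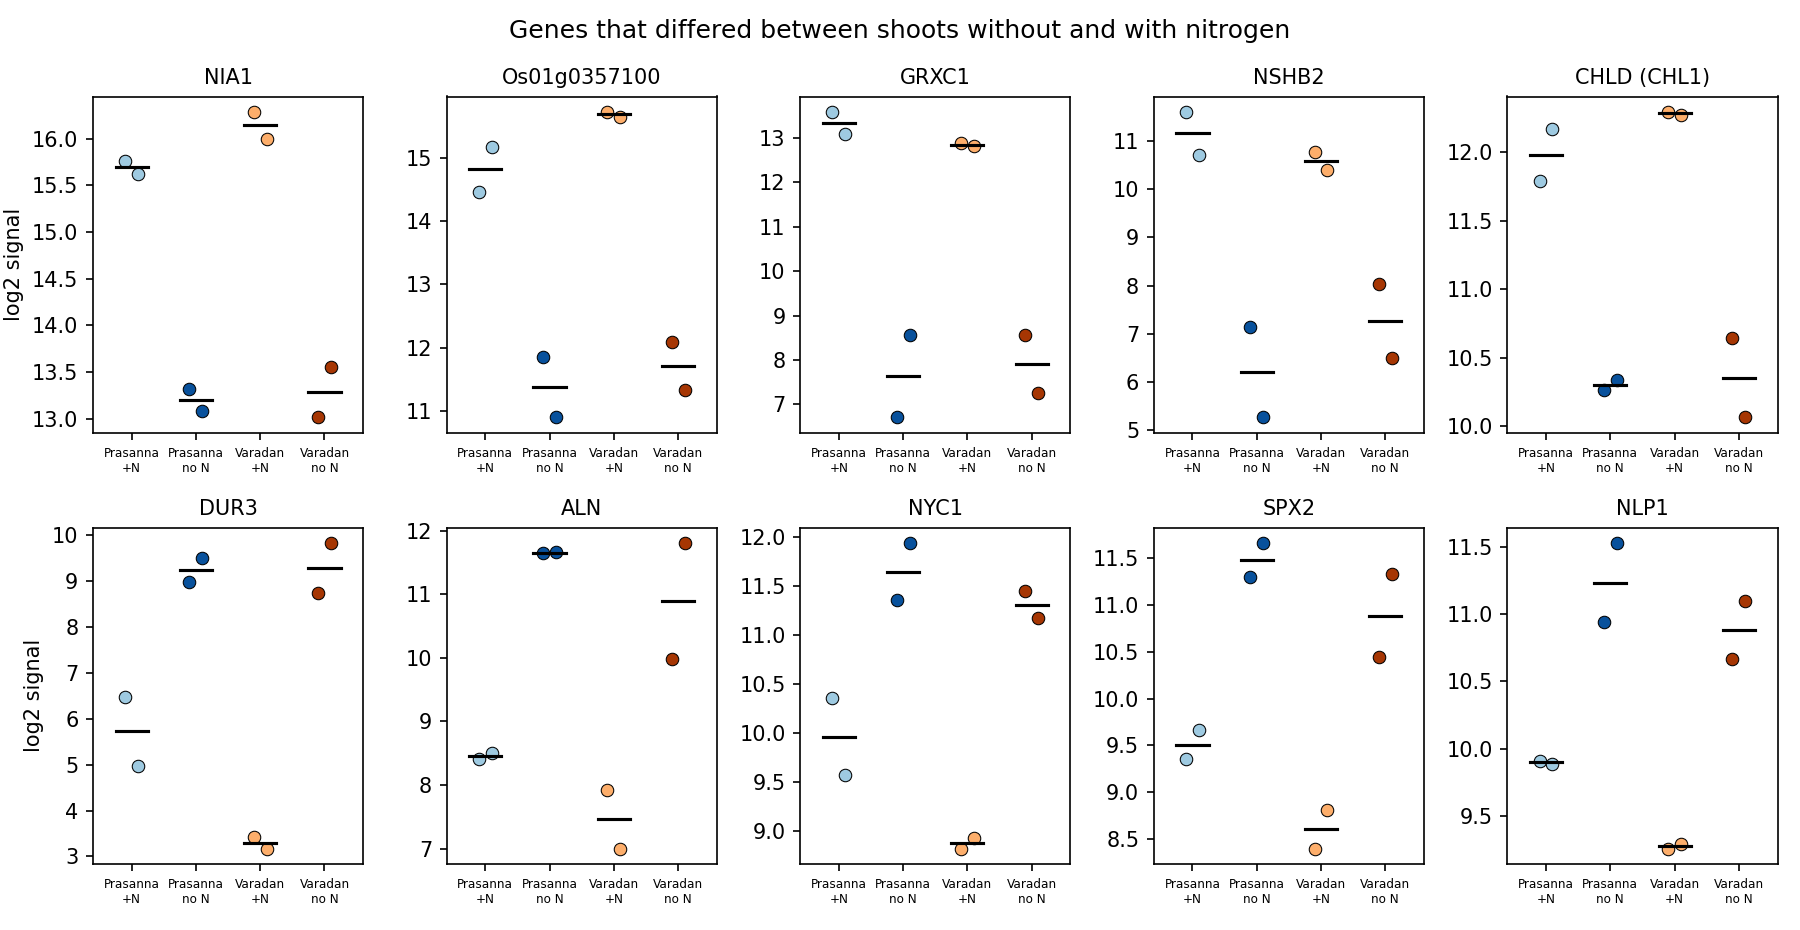
Log2 signal of 10 genes on each of the 8 arrays (points) with the mean of each group (bars), for Prasanna and Varadan with supplemented nitrogen (+N) or no nitrogen. NIA1 (NR1), Os01g0357100, GRXC1, NSHB2 (HB2) and CHLD (CHL1) lie lower without nitrogen in both varieties and DUR3, ALN, NYC1 and SPX2 higher, while NLP1 is also drawn higher but has an adjusted p of 0.0648.

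Of the 34333 probe sets tested, 63 passed for this average effect with limma, 21 of them higher and 42 lower without nitrogen, and 4606 had an unadjusted p under 0.05 against 1717 by chance. The model takes the arrays as independent, while the first no-nitrogen arrays of both varieties deviated together from their replicates. That shared part does not cancel in the average, so its errors and p-values may be too small. The 63 probe sets covered 54 loci, most known by identifier alone. Among loci named after their values were seen, Os12g0438600 fell by 5.96 ± 0.58 and Os01g0822800 rose by 3.90 ± 0.40 (adjusted p = 0.0328 and 0.0362). All 63 had the same sign in both varieties, which selection on the average favours, and 40 were larger in Varadan. The count was 0 without any 1 of the 4 supplemented arrays, 11 and 24 without replicate 1 and replicate 2 of Prasanna without nitrogen, and 36 without replicate 2 of Varadan without nitrogen. Without both first no-nitrogen arrays it was 1202, an alternative in which the spread rests on the supplemented arrays and the lone no-nitrogen arrays are assumed to vary like them, and it was 1 when the variance prior had no trend, 120 with array weights and 246 with nitrogen and variety as additive terms. Among the control probe sets the smallest limma adjusted p for this effect was 0.128, adjusted over the controls. Only the controls with the smallest unadjusted p, each at this value, are given here, and further controls may share it. An 18S and a 5' actin probe set, other than those behind the per-array control values above, stood at 1.21 and 2.01. The 25S control stood at -0.83, the Bacillus dap control at -0.86 and 6 bacterial bioC and bioD controls at -0.79 to -0.89.

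Within the nitrate list, 2 of 9 tested genes passed over all genes, both lower, and 3 passed when adjusted over the list alone. The third was Os02g0770800, a further nitrate reductase locus, at -5.06 ± 0.88 (adjusted p = 0.086). No transporter or transporter partner of the list passed, and they were not tested as a group against the reductases. NAR2.2, a partner protein of high-affinity nitrate transporters, stood at 3.34 ± 1.25 (adjusted p = 0.322), NAR2.1 at 1.46 ± 0.93, NRT2.3 at 0.64 ± 0.57 and NRT2.2 at -0.12 ± 0.40. The signal of NAR2.2 in supplemented Prasanna (3.94) lay under the filter level. Among 7 regulators tied to nitrogen supply, 0 passed over all genes (limma; 4 had an unadjusted p under 0.05) and 4 when adjusted over the list alone. These were Os03g0609500 at -4.32 ± 0.59, NLP1 at 1.48 ± 0.22, NIGT1 at -4.12 ± 1.09 and NLP2 at -0.92 ± 0.33, with adjusted p over all genes of 0.053, 0.0648, 0.202 and 0.305, and NIGT1 lay under the filter level in Prasanna without nitrogen (3.14). Of 20 genes of ammonium uptake and assimilation, 0 passed over all genes and 0 when adjusted over the list alone (6 had an unadjusted p under 0.05). The cytosolic glutamine synthetases GSR (GLN1-2) and RGS28 (GLN1-1) stood at -0.73 ± 0.18 and 1.04 ± 0.32, the plastid GS2 at -1.39 ± 0.51 and the ammonium transporter AMT3-3 at 1.80 ± 0.55. The camera adjusted p was 0.253 for the nitrate list, 0.261 for the regulators and 0.797 for the ammonium list. The nitrate list without both first no-nitrogen arrays passed downward at the preset correlation (adjusted p = 0.0177) and not with an estimated correlation (adjusted p = 0.786). The nitrate list had a median of 0.23 but a mean of -0.59 and a downward test.

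Of the 29 gene lists tested with camera at the preset correlation, 8 passed, 4 downward and 4 upward. All 17 tested genes of chlorophyll synthesis were lower without nitrogen (median -0.67; adjusted p = 2.67e-05, and adjusted p = 0.446 with an estimated correlation). Of these, 1 passed over all genes and 4 when adjusted over the list alone: CHL1, the divinyl reductase DVR (-1.17 ± 0.25), UPD2 (-0.88 ± 0.20) and CHL9 (-1.22 ± 0.28). Of 31 genes of the light reactions 30 were lower (median -0.85; adjusted p = 9.75e-08), and of 17 genes of carbon fixation and photorespiration 15 were lower (median -1.29; adjusted p = 9e-05). For both, adjusted p = 0.514 with an estimated correlation. No light-reaction gene passed over all genes or when adjusted over the list alone, and 13 had a limma unadjusted p under 0.05. PSB28 stood at -2.70 ± 0.74 and RCABP69, a light-harvesting protein, at -1.11 ± 0.35. In the carbon fixation list 0 passed over all genes and 4 when adjusted over the list alone, 3 lower, among them Os12g0292400 at -1.51 ± 0.24 and the glycine decarboxylase subunit GDCSH at -1.18 ± 0.33, and 1 higher, the glycolate oxidase GLO3 at 1.14 ± 0.31. Of 24 aquaporins 18 were lower (median -0.67; adjusted p = 0.0206, and adjusted p = 0.514 with an estimated correlation), with TIP2-2 at -1.60 ± 0.31 and TIP4-2, of opposite sign, at 2.44 ± 0.50. No aquaporin passed over all genes (10 had a limma unadjusted p under 0.05), and 4 did when adjusted over the list alone, 3 lower and 1 higher. The aquaporin call ended after quantile normalization, at an adjusted p of 0.131.

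Genes of chlorophyll breakdown and senescence were higher without nitrogen in 9 of 10 cases (median 0.93; adjusted p = 9e-05, and adjusted p = 0.514 with an estimated correlation, as for the other 3 upward lists). NYC1 passed over all genes and 7 passed when adjusted over the list alone, among them the stay-green gene SGR at 1.73 ± 0.39 and Os03g0327800 at 1.99 ± 0.26 (adjusted p over all genes 0.14 and 0.0511). Of 33 phenylpropanoid genes 24 were higher (median 0.39; adjusted p = 0.00384 and, with an estimated correlation, 0.514), and 8 higher and 1 lower passed when adjusted over the list alone against 0 over all genes. Among them were the 4-coumarate:CoA ligase Os4CL3 at 1.32 ± 0.20, the cinnamyl alcohol dehydrogenase CAD at 1.52 ± 0.33 and the laccase LAC3 at 1.44 ± 0.35. Of 36 jasmonate genes 26 were higher (median 0.66; adjusted p = 0.00681 and, with an estimated correlation, 0.514), with 0 past over all genes and 0 when adjusted over the list alone, and EG2 at 0.72 ± 0.18. Of 64 cell wall genes 46 were higher (median 0.35; adjusted p = 0.00727 and, with an estimated correlation, 0.514), and 4 passed when adjusted over the list alone against 0 over all genes: the cellulose synthases CESA8 (1.09 ± 0.18), CESA3 (0.995 ± 0.18) and CESA6 (0.92 ± 0.20) and TBL11 (1.19 ± 0.20). With limma's fry, the adjusted p was 0.0394 for chlorophyll synthesis and for the regulators tied to nitrogen supply, and 0.0523 for senescence. In the other comparisons fry passed 1 list, the regulators for variety without nitrogen (adjusted p = 0.0247, median 0.22), and the smallest fry adjusted p was 0.245 for nitrogen in Prasanna, 0.0949 in Varadan, 0.953 for the difference of the nitrogen effects and 0.302 for variety with supplemented nitrogen.

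In several of these lists the no-nitrogen replicates differed. The mean deviation of the light-reaction genes from the mean of the 8 arrays was -0.69 in Prasanna and -1.30 in Varadan on the first no-nitrogen array, against 0.02 and 0.25 on the second. For carbon fixation it was -1.08 and -1.50 against 0.21 and 0.26, and for aquaporins -0.81 and -0.81 against -0.02 and 0.16. Jasmonate genes stood at 0.68 and 1.21 on the first arrays against -0.38 and -0.15, cell wall genes at 0.40 and 0.48 against -0.19 and -0.04, and WRKY genes, whose list did not pass, at 0.45 and 1.26 against -0.72 and -0.12. The nitrate list, which did not pass either, stood at 0.57 and 0.49 on the first arrays against -1.47 and -0.76, and the regulators tied to nitrogen supply at -0.53 and -0.05 against -1.15 and -0.68. Senescence genes stood at 0.41 and 0.28 on the first arrays against 0.56 and 0.49 on the second, and chlorophyll synthesis at -0.48 and -0.69 against -0.15 and -0.25. Without both first arrays the light-reaction, carbon fixation, chlorophyll synthesis and senescence lists passed at the preset correlation and did not with an estimated correlation (adjusted p = 0.786 for each), while aquaporins (adjusted p = 0.219), the cell wall (adjusted p = 0.513), jasmonate (adjusted p = 0.459) and phenylpropanoids (adjusted p = 0.117) did not. Besides the nitrate list, cytosolic ribosomal proteins (downward, adjusted p = 0.000649), phosphate starvation (upward, adjusted p = 0.0252) and organic acids (upward, adjusted p = 0.0266) gained a call there, each with an adjusted p of 0.786 with an estimated correlation.

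**Figure D2:**
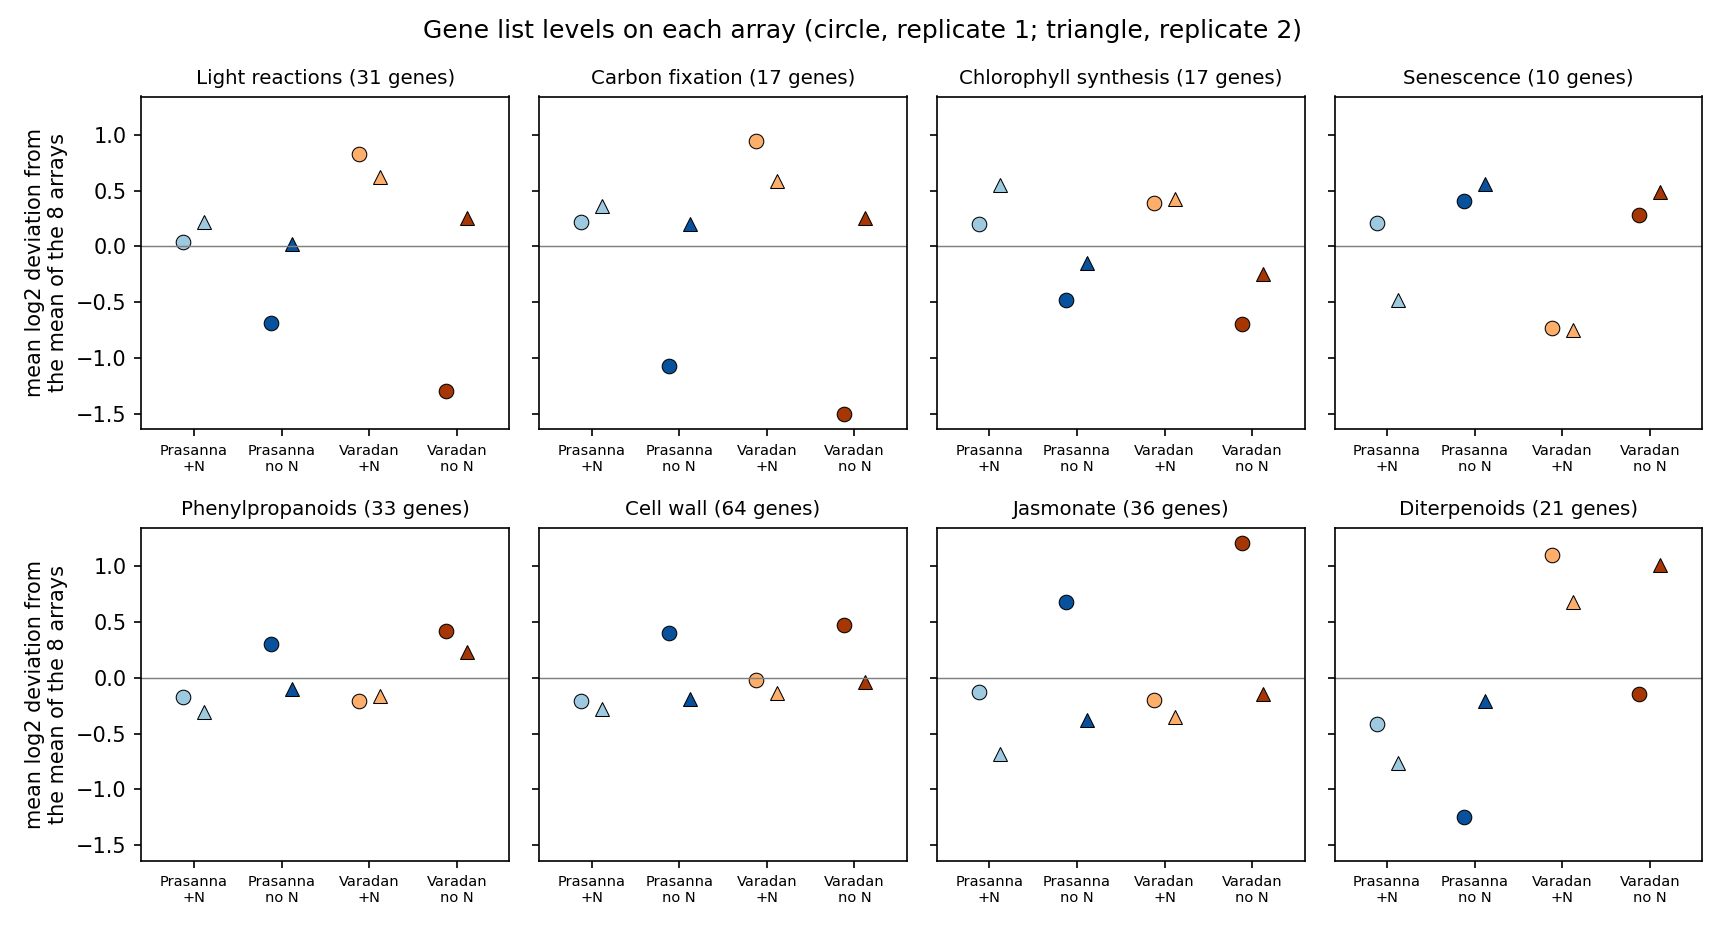
Mean log2 deviation of the tested genes of 8 lists from their mean over the 8 arrays, on each array (circles, replicate 1; triangles, replicate 2; colours, the 4 groups). The light reactions lie at -1.30 on the first and 0.25 on the second array of Varadan without nitrogen, while senescence genes lie at 0.28 to 0.56 on all 4 no-nitrogen arrays.

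The other lists did not pass for the average nitrogen effect. Cytosolic ribosomal proteins had 21 of 25 genes lower by a median of -0.13 (adjusted p = 0.0501), and organic acid enzymes 14 of 17 higher by a median of 0.32 (adjusted p = 0.133). Auxin genes had a median of 0.10 (adjusted p = 0.145), and phosphate starvation genes one of 0.27 (adjusted p = 0.157), with SPX2 past over all genes and the lipid synthase MGD3 (1.61 ± 0.29) joining it when adjusted over the list alone. The adjusted p was 0.241 for diterpenoids (median -0.36), 0.261 for metal transport (-0.07) and for WRKY factors (0.64), and 0.334 for heat shock genes (-0.05). Metal genes that passed when adjusted over the list alone were 4 lower, with the iron regulator IRO3 at -1.78 ± 0.25, Nramp1 at -3.02 ± 0.45 and YSL15 at -3.44 ± 0.58, and 1 higher, against 0 over all genes. The adjusted p was 0.414 for amino acid carriers (0.43) and for autophagy (0.11), 0.468 for cytokinin (-0.09) and 0.498 for starch and sucrose (-0.12). Of the amino acid carriers Os01g0882800 rose by 1.85 ± 0.24 (adjusted p = 0.0498), and 4 passed when adjusted over the list alone. The cytokinin response regulators RR9 (-1.97 ± 0.30), RR4 (-1.44 ± 0.23) and RR2 (-1.88 ± 0.41) passed when adjusted over the list alone and not over all genes. The adjusted p was 0.602 for defence (-0.15) and NAC factors (0.05), 0.801 for glutathione S-transferases (-0.06), 0.869 for proteases (-0.15) and for LEA and abscisic acid genes (0.19), and 0.954 for the cell cycle (-0.01). LEA1 (-4.53 ± 0.83), RAB16C (-3.83 ± 0.71) and LEA (-3.99 ± 0.80), proteins of dehydrated or maturing tissue, passed when adjusted over their list alone. The mean of that list was -0.47 and its test downward, against the positive median, and the cell cycle list had a mean of -0.04 and an upward test. Of 3 peroxidases PRX74 stood at 1.34 ± 0.28, while the mean of the 3 went the other way. Its deviation was -1.52 and -0.93 without nitrogen against 0.31 and 0.17 with it in Prasanna. In Varadan it was 0.29 and 0.50 against 0.57 and 0.61. The 4 root markers stood at -0.49 ± 0.49 (QHB), -0.20 ± 0.22 (Lsi1), 0.45 ± 0.72 (RAA1) and 0.08 ± 0.53 (WOX11).

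The next question was the nitrogen effect within each variety. Within Prasanna, the sugar transporter SWEET3A stood at 5.39 ± 0.93 and DUR3 at 3.52 ± 0.64, and GRXC1 at -5.70 ± 0.65, NR1 at -2.50 ± 0.29, HB2 at -4.97 ± 0.74 and RAB16C at -6.23 ± 1.0, the most extreme of its 3 probe sets, which reached up to -1.06. The homeobox gene HOX4 (1.48 ± 0.27), XBOS31 (1.88 ± 0.34), the auxin response factor ARF1 (1.95 ± 0.36, with 1.20 on its other probe set) and BURP2 (-3.76 ± 0.52, with -1.40 on its other probe set) were also named by the rule. The supplemented Prasanna signal of SWEET3A (2.60) lay under the filter level, so its size rests on a background signal. None passed, as 0 probe sets did with limma (smallest adjusted p 0.133) and 2276 had an unadjusted p under 0.05 against 1717 by chance. The count was 5, all lower, without either array of Varadan without nitrogen, and 296 without both first no-nitrogen arrays. Of the gene lists 8 passed with camera. Senescence (9 of 10 higher, median 0.90; adjusted p = 0.0011) and auxin genes (47 of 65 higher, median 0.41; adjusted p = 0.00913) were upward, as were the cell wall (median 0.35; adjusted p = 0.0209) and phenylpropanoids (median 0.65; adjusted p = 0.0269). Chlorophyll synthesis (14 of 17 lower, median -0.76; adjusted p = 0.000716), light reactions (27 of 31 lower, median -0.37; adjusted p = 0.0188), carbon fixation (median -0.89; adjusted p = 0.0211) and aquaporins (median -0.64; adjusted p = 0.0211) were downward. None of the 8 passed with an estimated correlation, with an adjusted p between 0.668 and 0.819. After quantile normalization the light reactions, carbon fixation and aquaporins did not pass, and without both first no-nitrogen arrays these 3, the cell wall and phenylpropanoids did not, while the cell cycle (upward, adjusted p = 0.000494), nitrate (downward, adjusted p = 0.00242) and cytosolic ribosomal (downward, adjusted p = 0.0184) lists did. With an estimated correlation these 3 had an adjusted p of 0.905, 0.803 and 0.905.

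Within Varadan alone, DUR3 stood at 6.0 ± 0.64, NYC1 at 2.43 ± 0.36, ALN at 3.43 ± 0.59, SPX2 at 2.28 ± 0.37 and Os4CL3 at 1.56 ± 0.28, with 3 probe sets from 0.44 to 1.56. NR1 stood at -2.86 ± 0.29, GRXC1 at -4.93 ± 0.65, the peroxiredoxin PRXIIE-2 at -1.89 ± 0.27, CHL1 at -1.94 ± 0.29 and IRO3 at -2.02 ± 0.36. None of these passed (adjusted p from 0.153 to 0.294), and the size for DUR3 rests on a supplemented signal under the filter level. The 1 probe set that passed with limma, of 3068 with an unadjusted p under 0.05, belongs to Os06g0473000, named after its value was seen, which fell by 9.85 ± 0.62 (adjusted p = 0.0217). Its signal was 11.06 ± 0.20 (SD, n = 2) with nitrogen and 1.22 ± 0.19 without, the latter under the filter level of 4.48, so the size of the fall rests on a background signal. In Prasanna it stood at -7.61 ± 0.62 (adjusted p = 0.133), where the signal without nitrogen (3.50) also lay under the filter level. The call was absent, with 0 probe sets past, without any 1 of the 4 supplemented arrays or replicate 1 of Varadan without nitrogen. Without replicate 2 of that group 1 probe set passed, a different one. The count was 0 with no variance trend and with the 4 Varadan arrays alone, and 370 without both first no-nitrogen arrays. Of the gene lists 9 passed with camera. All 31 light-reaction genes were lower (median -1.25; adjusted p = 1.15e-10), with carbon fixation (15 of 17 lower, median -1.69; adjusted p = 1.92e-05), chlorophyll synthesis (16 of 17 lower, median -0.53; adjusted p = 0.000141) and cytosolic ribosomal proteins (24 of 25 lower, median -0.22; adjusted p = 0.00562). Senescence (8 of 10 higher, median 1.22; adjusted p = 0.000455), jasmonate (30 of 36 higher, median 0.71; adjusted p = 0.00209), phenylpropanoids (median 0.41; adjusted p = 0.00279), organic acids (13 of 17 higher, median 0.35; adjusted p = 0.0197) and the cell wall (median 0.28; adjusted p = 0.0312) were upward. None passed with an estimated correlation, with an adjusted p between 0.597 and 0.803, and the ribosomal call ended after quantile normalization (adjusted p = 0.309). Without both first no-nitrogen arrays the jasmonate (adjusted p = 0.357), cell wall (adjusted p = 0.63) and phenylpropanoid (adjusted p = 0.0602) lists did not pass, while the nitrate (downward, adjusted p = 0.0356) and phosphate (upward, adjusted p = 0.0042) lists did, both with an adjusted p of 0.777 with an estimated correlation.

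The nitrogen effects of the varieties, which share no arrays, correlated at r = 0.351 across the probe sets, which are not independent replicates. No probe set passed in both with limma. At an unadjusted p under 0.05, 855 probe sets moved in the same direction in both and 11 in opposite directions, against 101.6 and 101.8 for independent lists. That expectation leaves out that both comparisons use the same estimate of the spread for each probe set. It also leaves out that the first no-nitrogen arrays of the varieties deviated together from their replicates. Without both of these arrays r was 0.25. The second no-nitrogen arrays, which remain there, correlated at 0.909 with each other, so a deviation shared by the varieties may not be removed.

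**Figure D3:**
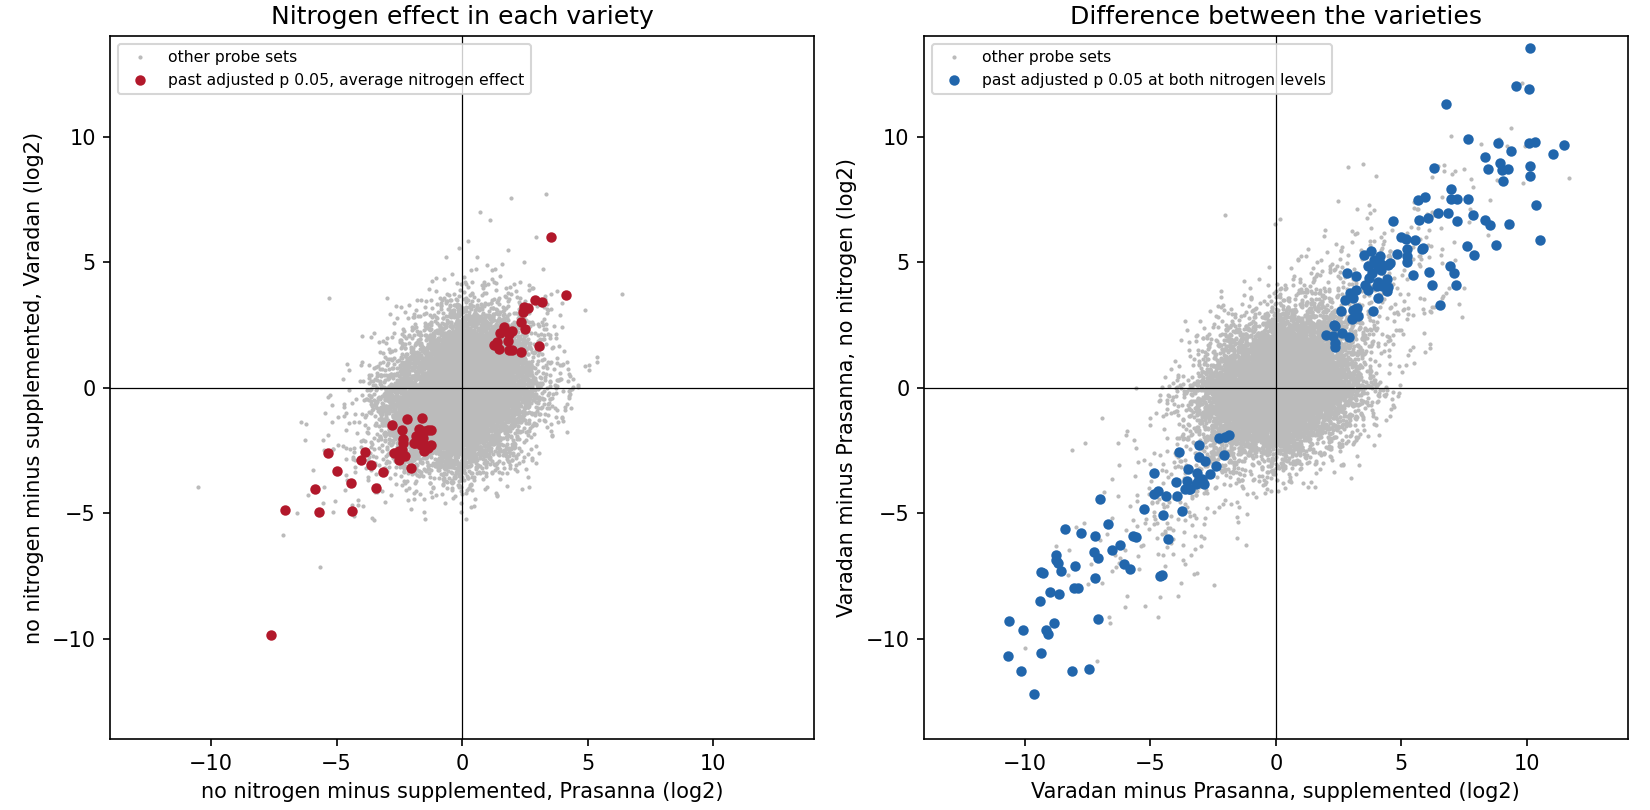
Log2 effect of no nitrogen in Varadan against Prasanna (left; red, the 63 probe sets past the threshold for the average effect) and log2 difference between the varieties without against with nitrogen (right; blue, the 172 probe sets past the threshold at both levels). Each grey point is another tested probe set, and all coloured points lie in the quadrants of equal sign.

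The series title speaks of a contrasting response, which the difference between the nitrogen effects tests directly. For 29 of 31 light-reaction genes the effect was more negative in Varadan, by a median of -0.78 (camera adjusted p = 1.5e-05), among them RCABP69 (-1.09 ± 0.71) and the plastocyanin PETE (-0.65 ± 0.43). All 17 carbon fixation genes leaned the same way (median -0.77), with RBCS1, a small subunit of Rubisco, at -0.77 ± 0.49, as did 51 of 65 auxin genes (median -0.22) and 67 of 88 cell cycle genes (median -0.21), each with an adjusted p of 0.0191. None of these 4 lists passed with an estimated correlation (adjusted p = 0.864), and 0 of their genes passed over all genes or when adjusted over the list alone. Without both first no-nitrogen arrays the light-reaction median was -0.33 (adjusted p = 0.00826, and adjusted p = 0.902 with an estimated correlation). Light-reaction genes were also higher in Varadan than in Prasanna with supplemented nitrogen, on arrays that enter both comparisons, and the carbon fixation call ended after quantile normalization (adjusted p = 0.235).

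For single genes, 0 probe sets passed with limma for a difference in the nitrogen effect, and 714 had an unadjusted p under 0.05 where chance gives 1717. The median standard error was 0.784 (log2), which limits what can pass. The part of the deviation that the first no-nitrogen arrays of both varieties share cancels in this difference but enters the spread. The errors of this comparison may therefore be too large. By rule, the genes named on the positive side, with a less negative or more positive effect in Varadan, were OsCASPL1C1 (5.26 ± 1.16), Lhs1 (4.39 ± 1.27), RAB16C (4.81 ± 1.41), YSL2 (2.56 ± 0.77) and LAC15 (2.92 ± 0.92). LAC15 has 3 probe sets that ranged from -1.73 to 2.92, and the 3 of RAB16C ranged from 1.67 to 4.80. On the negative side stood SWEET3A (-4.38 ± 1.32), TBL3 (-4.06 ± 1.22), OsC3H3 (-2.10 ± 0.62), SPL4 (-1.73 ± 0.45) and PRXIIE-2 (-1.52 ± 0.38), and the 4 probe sets of SPL4 ranged from -1.73 to 0.86. OsCASPL1C1, Lhs1, LAC15, TBL3 and SWEET3A each lay under the filter level in at least 1 group. The adjusted p was 1 for all of them, and the count stayed at 0 in every alternative run, including without each array in turn.

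A further question was how the varieties themselves differ with supplemented nitrogen. ASMT, which forms melatonin from N-acetylserotonin, was higher in Varadan by 8.92 ± 0.97 on the log2 scale (adjusted p = 0.0113) and the MAP kinase gene MPK15 by 8.54 ± 0.76 (adjusted p = 0.00411). Their signals in Prasanna were 1.60 ± 1.74 and 0.38 ± 0.25 (SD, n = 2), under the filter level of 4.48, so these sizes rest on background signals. The mannanase MAN7 was higher by 5.72 ± 0.87, the kinase genes WNK7 and CRK10 by 3.66 ± 0.33 and 3.34 ± 0.53, and the histone H2B.10 by 2.91 ± 0.29 (adjusted p from 0.00474 to 0.0499). YSL2, a carrier of metal-nicotianamine complexes, was lower in Varadan, at -7.01 ± 0.55 (adjusted p = 0.00263), with signals of 6.33 ± 0.58 against 13.34 ± 0.78. HSP16.0 (-6.85 ± 1.09), HCT4 (-4.39 ± 0.76), the kaurene synthase-like gene KS2 (-5.06 ± 0.89) and MYBS1 (-1.51 ± 0.28) did not pass (adjusted p from 0.0506 to 0.0866), and the first 3 lay under the filter level in supplemented Varadan. In all, 238 probe sets of 187 loci passed with limma, 146 higher and 92 lower in Varadan, and 2640 had an unadjusted p under 0.05. The count was 86 and 81 without replicate 1 and replicate 2 of supplemented Prasanna, 64 and 42 without those of supplemented Varadan, 129 with the filter at the 60th percentile, 572 with array weights and 739 without both first no-nitrogen arrays.

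Of the gene lists, 3 passed, all higher in Varadan with supplemented nitrogen: diterpenoid synthesis (16 of 21 genes, median 2.05; adjusted p = 0.000423), the light reactions (29 of 31 genes, median 0.64; adjusted p = 0.000423) and defence proteins (15 of 18 genes, median 0.52; adjusted p = 0.0183). For each, adjusted p = 0.986 with an estimated correlation. Diterpenoid synthesis yields the phytoalexins and the precursors of gibberellin. None of its genes passed over all genes and 5 did when adjusted over the list alone. KO1 stood at 3.70 ± 0.76, CYP76M6 at 4.16 ± 1.17, CYP99A2 at 3.31 ± 0.96 and CYP76M8 at 2.75 ± 0.77, while KS2 was of opposite sign. The defence genes LTP (1.24 ± 0.27), GCH7 (1.16 ± 0.30) and NH3 (1.11 ± 0.29) passed when adjusted over the list alone, against 0 over all genes. No light-reaction gene passed either way, and that call ended after quantile normalization (adjusted p = 0.101). Carbon fixation (upward, adjusted p = 0.000904) and organic acids (downward, adjusted p = 0.0371) passed as well without both first no-nitrogen arrays, both with an adjusted p of 0.955 with an estimated correlation. The GAPDH control's 3' to 5' difference was 2.77 and 2.93 on the supplemented Prasanna arrays and 4.24 and 4.78 on those of Varadan. For the cyclophilin control it was 1.169 and 1.236 against 1.325 and 1.62, and for ubiquitin 0.319 and 0.339 against 0.666 and 0.734. For actin the varieties overlapped, with 4.764 and 4.891 against 4.737 and 5.008. The root marker RAA1 stood at 1.68 ± 1.01 and, in the cell cycle list, H2B.10 passed over all genes and MCM9 (3.19 ± 0.57) joined it when adjusted over the list alone.

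The last question was how the varieties differ without nitrogen. ASMT was higher in Varadan by 8.93 ± 0.97 (adjusted p = 0.0104), MPK15 by 6.48 ± 0.76 (adjusted p = 0.0128) and WNK7 by 3.89 ± 0.33 (adjusted p = 0.00404). The hydroxycinnamoyltransferase HCT3 was higher by 4.59 ± 0.44, the laccase LAC15 by 4.55 ± 0.65, with its 3 probe sets from -0.73 to 4.55, and BURP2 by 3.40 ± 0.52, with 1.17 on its other probe set (adjusted p from 0.00616 to 0.0392). KS2 was lower in Varadan, at -5.63 ± 0.89 (adjusted p = 0.0459), and so was YSL2, at -4.44 ± 0.55 (adjusted p = 0.0161). The signals of ASMT (1.42), MPK15 (2.23) and LAC15 (4.23) in Prasanna and of KS2 (3.32) in Varadan lay under the filter level of 4.48, so these sizes rest on background signals. RXY1 (-2.27 ± 0.42), MYBS1 (-1.35 ± 0.28) and SPL4 (-1.44 ± 0.32) did not pass, and their probe sets ranged from -2.27 to 0.58 for RXY1 and from -1.44 to 0.54 for SPL4. In all, 262 probe sets of 202 loci passed with limma, 150 higher and 112 lower, and 2183 had an unadjusted p under 0.05. Diterpenoid synthesis (17 of 21 higher, median 1.76; adjusted p = 0.0044) and defence proteins (12 of 18 higher, median 0.86; adjusted p = 0.0375) were the lists that passed, with adjusted p = 0.854 for both with an estimated correlation. In the diterpenoid list KS2 passed over all genes, and 5 genes passed when adjusted over the list alone, with CYP701A9 at 4.61 ± 1.19, CPS4 at 4.43 ± 1.25 and KO1 at 2.83 ± 0.76. CYP701A9 (2.64) and CPS4 (3.91) lay under the filter level in Prasanna. The mean deviation of the list was -1.25 and -0.15 on the first no-nitrogen arrays of Prasanna and Varadan and -0.21 and 1.01 on the second. No defence gene passed either way, with 0.84 ± 0.27 for LTP, and the defence call ended without both first no-nitrogen arrays (adjusted p = 0.598), where the cell cycle list passed downward (adjusted p = 0.0486, and adjusted p = 0.819 with an estimated correlation). The GAPDH control's 3' to 5' difference was 2.77 and 2.79 on these Prasanna arrays and 3.87 and 4.11 on those of Varadan. For the actin, cyclophilin and ubiquitin controls the values of the varieties overlapped here. RAA1 stood at 2.51 ± 1.01. Leaving out 1 array gave 158 to 194 probe sets, and the count fell below 262 by over 1.5 times without replicate 1 of Prasanna without nitrogen (163), replicate 2 (170), the supplemented Prasanna arrays (165 and 173), replicate 2 of Varadan without nitrogen (172) and the supplemented Varadan arrays (164 and 158), and it was 155 with array weights and 173 with the filter at the 60th percentile.

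**Figure D4:**
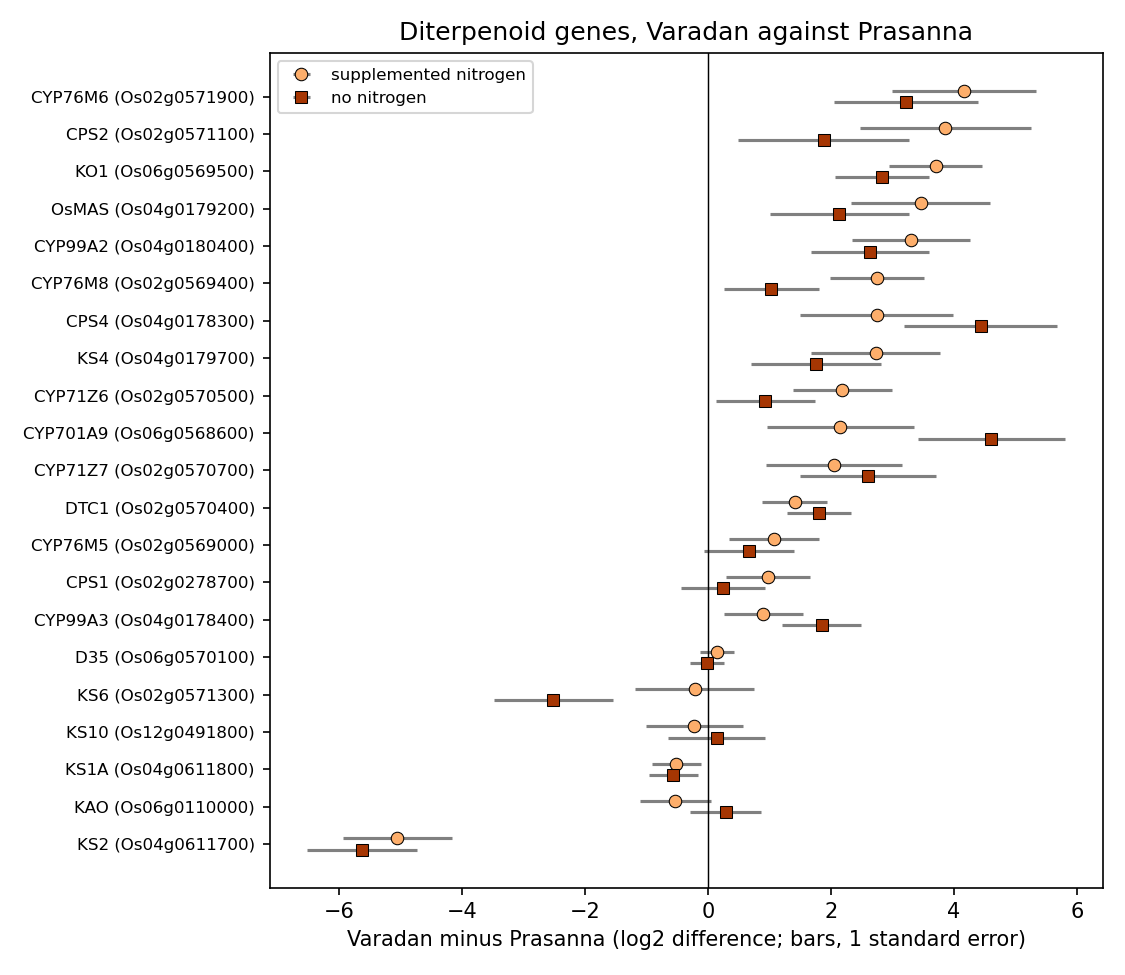
Log2 difference of Varadan minus Prasanna for the 21 tested diterpenoid genes, with supplemented nitrogen (circles) and no nitrogen (squares); bars are 1 standard error. Most genes lie to the right of 0 at both levels, while KS2 lies at -5.06 and -5.63.

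At both levels 172 probe sets passed, 102 higher and 70 lower in Varadan, all in the same direction, where independent lists would share 0.638 and 0.3. These comparisons share no arrays but use the same estimate of the spread for each probe set, so their lists are not independent. Their log2 differences correlated at r = 0.522 across probe sets. The median size of the difference over the 172 was 5.65. For 51 of them (29.7%) the variety with the lower signal lay under the filter level, so its probe set signal was near background.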

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

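The tests without the first no-nitrogen arrays (with the bounds set for them), with an estimated correlation, of a shared replicate 1 batch, of the 18S control and of the 3' to 5' differences were chosen only after the results were seen. In 4 gene lists the test of the difference between the varieties' nitrogen effects passed at the preset correlation, and in none of them with an estimated correlation (adjusted p = 0.864 for each). The median difference of Varadan minus Prasanna was -0.775 for the light reactions, -0.773 for carbon fixation with photorespiration, -0.221 for auxin and -0.209 for the cell cycle (log2). After quantile normalization carbon fixation did not pass (adjusted p = 0.235).

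For the light reactions, 29 of 31 genes had a more negative nitrogen effect in Varadan. Brightness of the probe sets as the whole cause is argued against by genes of matched mean signal outside the photosynthesis lists. Their median was -0.225 (SD over draws 0.077), and 0 of 10000 draws were as low as -0.775. The draws took genes independently, while the correlation estimated between genes of the list was 0.716. They therefore understate how far the list median can vary by chance. Without both first no-nitrogen arrays the median was -0.325 with an adjusted p of 0.00826, but 0.902 with an estimated correlation, so whether these arrays are its whole cause cannot be told apart. Variation between arrays shared by coregulated genes stays open, as the adjusted p was 0.864 with the correlation estimated from the data. A difference between the varieties in their response to nitrogen stays open as untested beyond these arrays.

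The first no-nitrogen arrays of both varieties deviated from their replicates together, with a correlation of 0.460 across probe sets. Whether the first or the second arrays depart cannot be told from 2 arrays per group. A replicate 1 batch shared by all 4 groups is argued against by 0.022 for the same correlation between the supplemented groups, although the 18S and 28S controls were brighter on the first array in all 4 groups. Whether ribosomal RNA or degraded RNA on these arrays alone played a part could not be decided. The 18S difference was 1.073 log2 in supplemented Prasanna but larger without nitrogen within each variety (1.974 in Prasanna, 0.909 against 0.660 in Varadan). The 28S difference was 0.785 against 0.758 in Prasanna and 0.975 against 0.233 in Varadan. Both controls thus rose in the supplemented groups too, and only a further rise without nitrogen stays open. Degraded RNA on the first arrays would raise their 3' to 5' difference. Its mean over 4 controls, first minus second array, was -0.572 ± 0.281 and -0.055 ± 0.125 (SE) without nitrogen in Prasanna and Varadan, with controls of both signs in each. With supplemented nitrogen it was -0.014 ± 0.062 and -0.294 ± 0.097. Neither mean without nitrogen was raised, but that of Varadan was smaller than its error. A mix-up of samples was not tested, and NR1 and DUR3, which lay on the no-nitrogen side on both no-nitrogen arrays of each variety, were chosen for that difference. Whether a stronger loss of nitrogen in the first replicates was the whole cause could not be decided. The Prasanna deviation correlated at -0.086 with the nitrogen effect of Varadan on its second no-nitrogen array. That is under 0.1, the bound written beforehand for arguing against this cause, and the value was -0.151 the other way round. Anything the second no-nitrogen arrays share lowers both values, and these arrays stood together on principal component 3 (98.7 and 108.6). The 63 probe sets of the average effect deviated toward the nitrogen effect by a median of 0.03 in Prasanna and -0.199 in Varadan. Their selection on these same arrays favoured a small spread between replicates, so these medians are no further support. With both no-nitrogen arrays the correlation was 0.232, a value that the shared deviation raises if it lies in the first arrays, while the values on the second arrays are lowered if those carry part of it. A batch of the first no-nitrogen arrays alone was not tested and stays open, and no other biological explanation was tested.

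Between the varieties, 172 probe sets passed at both nitrogen levels. A sequence difference of a variety under single probe sets cannot be told apart from a difference in expression for these as a set. Of 74 other probe sets of the same loci, 60 differed in the same direction and 48 (64.9%) did so by 1 log2 or more, which leaves both open. The rest had the opposite sign. On average over the nitrogen levels, probe sets of Os12g0552500 stood at 10.98, -1.02, -9.09 and -8.58, and those of Os07g0468100 at -6.53 and 6.42. Several that agreed carry the same target name as the first probe set of the locus, so they are not independent of it. For the other loci no second probe set was tested. A difference in expression between the varieties stays open as untested by another assay.

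For the count of 63 probe sets in the average nitrogen effect, chance was not excluded by the count over all 35 splits of the 8 arrays into 4 and 4, as fixed beforehand. With variety as a term the nitrogen split gave 246 probe sets, and 2 of the 35 splits gave as many, the nitrogen split included. The other, with 732, is the split by variety, which was fitted without the variety term and points to a structure of the samples. The remaining 33 splits gave 0.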

How the results depend on the processing

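Leaving out both first no-nitrogen arrays and the additive model were chosen only after the results were seen. Of 199 gene values 0 reversed under any alternative run, some of which covered 10, 11, 88 or 169 of them. This was largely fixed in advance. The filters, the variance prior, the replicate block and the array weights, equal within each group, leave the differences as they were. Genes named by the rule outside the interaction and the gene lists had arrays that did not overlap, so leaving out 1 array could not turn their sign. Members of gene lists were taken by p alone, without that condition. Of the 68 past the threshold, 33 stayed past without a variance trend, 23 to 56 without 1 array and 61 to 67 after quantile normalization, subtracted medians, no filter or array weights. The interaction count was 0 in all alternatives run for it (limma; 310 to 1851 at an unadjusted p under 0.05). Counts are given for the nitrogen effect in Prasanna (0), in Varadan (1) and on average (63), and for variety with (238) and without nitrogen (262). Without each array in turn they were 0 to 5, 0 to 1, 0 to 84, 42 to 278 and 158 to 194, with fewer arrays and the lone array of a group assumed to vary like the others. Without both first no-nitrogen arrays they were 296, 370, 1202, 739 and 351, and 5 gene lists instead of 3 passed at the preset correlation for variety with nitrogen. Without a variance trend the count was 0 in Varadan and 1 on average, and with the 4 Varadan arrays alone 0. Array weights gave 120 on average, 572 for variety with nitrogen and 155 without. The filter at the 60th percentile, which tests fewer probe sets, gave 129 and 173 for variety with and without nitrogen, and the additive model 246 on average. With an estimated correlation 0 gene lists passed in each of the 6 comparisons, from 8, 9, 8, 4, 3 and 2, and after quantile normalization 5 passed in Prasanna. Where the construction does not show it, the cause was not tested. Quantile normalization, subtracted medians and no filter left the counts within 1.5 times. The series-matrix values gave nothing separate, as they were identical to within 3.0e-08. Gene lists were not run without single arrays, and no fit left out both second no-nitrogen arrays. MAS5 signals near background have a large spread on the log2 scale, which limits dim probe sets.

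With the replicate number as a block, 150 probe sets passed for the average nitrogen effect, all 63 among them. The deviations of first replicates correlated at 0.460 between the no-nitrogen groups and at -0.039 to 0.109 between other pairs, so the numbers do not pair the samples across all groups.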
